A study of Homo sapiens with 6 samples.

How the data were processed

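The series holds 6 one-colour Agilent expression arrays of HepG2, a human hepatoma cell line. One array carried RNA of control cells, and 1 array each carried RNA of cells exposed to an extract of Scutellaria baicalensis, a plant of the mint family, at 100 µg/ml for 1, 3, 6, 12 or 24 h. Each group held 1 array, so no comparison had a spread between replicates, and no difference at a single time has a p-value. The labels give no time for the control, which was placed at 0 h of exposure by assumption. No control array matched to the later times was analysed here.

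RNA was purified with an RNeasy kit and amplified and labelled with Agilent's Low RNA Input Linear Amplification kit PLUS, per the labels' protocols. The labels name the dye Cy5, whereas the scanner files hold columns of the green channel alone, per the file headers. The scanner files hold intensity values per spot, per the file headers, among them a processed signal that the scanner software had corrected for background. The deposited intensity values were not normalized between arrays. The scanner software's version and the genome build of the array's probes are not given in the sources used here, so no coordinates are reported. The authors' deposited value table held linear intensity for 35646 probes and was also unscaled. It matched the median signal of a spot minus the median of its local background within 0.51 units for at least 99.9% of probes on each array. Its column medians were 161.5 for the control and 226, 391, 40, 86 and 297.5 at 1, 3, 6, 12 and 24 h.

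The main values were log2 of the processed signal, averaged over the spots of a probe, minus the 75th percentile of each array. The 1639 control spots per array were left out, and 105 probes flagged as outliers on any array were dropped, which left 40895 of 41000 probes. Probes were named through a RefSeq gene table of the assembly GRCh38.p14, which was used for names only. A single symbol was found for 26810 probes, no match for 14170 and several symbols for 20. These probes covered 17521 genes, of which 17488 had a probe that was kept. A gene was represented by its probe with the highest mean over the 6 arrays. Log2 differences of treated minus control are given for genes well above background on both arrays, and counts of 2-fold differences also left out genes saturated on either array. Where a probe was saturated on both arrays its difference shows the scaling, not the RNA.

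Precision was limited by the number of arrays. The SD of log2 signal between the 10 spots of 264 repeated probes lay between 0.0599 and 0.0836 per array. Different probes of a gene disagreed more. From 3002 to 4736 genes with a pair of measured probes, the SD of a single probe's log2 difference was 0.35 at 1 h, 0.44 at 3 h, 0.77 at 6 h, 0.68 at 12 h and 0.69 at 24 h, and these values serve as the error of a single gene. Both probes were read on the same arrays, so this error leaves out any variation between cultures, labellings and arrays that they share. Pairs of probes that were at least 2-fold apart from the control in opposite directions numbered 53 at 6 h, 41 at 12 h and 45 at 24 h.

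A trend was tested with limma as the slope of log2 signal on log2(hours + 1) over all 6 arrays, for 13619 genes well above background on at least 3 arrays, with Benjamini-Hochberg adjustment at 0.05. This leaves 4 residual degrees of freedom, and the residual is the scatter about a line, not a spread between replicates. A second limma test used the linear and quadratic terms together. The 39 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01. At a preset correlation camera takes its degrees of freedom from the number of genes, not of arrays. Its p-values at that setting do not measure a spread between arrays. At each time a list's median difference was set against 10000 random lists of the same size matched on mean expression, and a list in the outer 2.5% on either side was called outside the range of matched lists. This percentile describes these arrays and is not a test between conditions. Named genes were, by a rule also fixed before the data were examined, the 6 most raised and 6 most lowered genes at each time among those at least 1.5-fold apart in the same direction at a neighbouring time, up to 4 members of each list with the largest differences, and a fixed set that included CYP1A1 and MYC. A few genes that the rule names are not reported here.

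On simulated data with the real means and residual SDs, the trend test recovered 0 of 50 genes given a 2-fold change over the 13619 genes, 5 of 50 at 4-fold, 13 of 50 at 8-fold and 38 of 50 at 32-fold, and called 3 unchanged genes. Among 300 random lists of 20 genes, 5% fell outside the range of matched lists at 3 h. The random lists came from the same genes as the matched lists. Their share therefore checks the procedure, and gives no error rate for lists whose members move together. Alternatives were quantile normalization, normexp background correction with an offset of 50, other filters, the mean of a gene's probes, the authors' deposited values, a 1.5-fold threshold, other time scales, and leaving out each array. Cyclic loess normalization, other treatments of saturated genes and leaving out the 6 h and 12 h arrays together were added after the data were seen. The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.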

Results

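Gene expression was measured in HepG2 human hepatoma cells on 6 one-colour Agilent arrays. One array held control cells, and 5 held cells exposed to a Scutellaria baicalensis extract at 100 µg/ml for 1, 3, 6, 12 or 24 h. The series asks how expression changes with the time of exposure. No group was replicated. Values are log2 differences of a treated array minus the control array, and the error given is the SD of a single probe's difference, estimated from pairs of probes of the same gene. This error holds no spread between cultures or arrays.

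The arrays differed in brightness. The 75th percentile of the processed signal was 768 units on the control array, and 1090, 1900, 153, 420 and 1640 at 1, 3, 6, 12 and 24 h, a 12.4-fold range. Control spots were dim at 6 h and 12 h too: their bright-corner signal was 10275 on the control array, 1790 at 6 h and 3370 at 12 h. The log2 signal of spike-in spots was 8.01, 5.65 and 6.87 there. Minus the log2 75th percentile, it was -1.57 on the control array and -1.81, -2.60, -1.61, -1.84 and -2.78 at 1, 3, 6, 12 and 24 h. Any overall shift of the cells' signal against the spike-ins is removed by scaling to that percentile. Probes well above background made up 69.8% on the control array, 49.5% at 6 h and 64.4% at 12 h, and between 70.5% and 73.2% on the other treated arrays. After scaling, the median of all measured genes lay 0.34 above the control at 6 h and 0.23 above it at 12 h, and list medians at these times are therefore given relative to matched random lists. Fitted lines, fitted changes and values of single genes are not corrected for this offset.

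**Figure D1:**
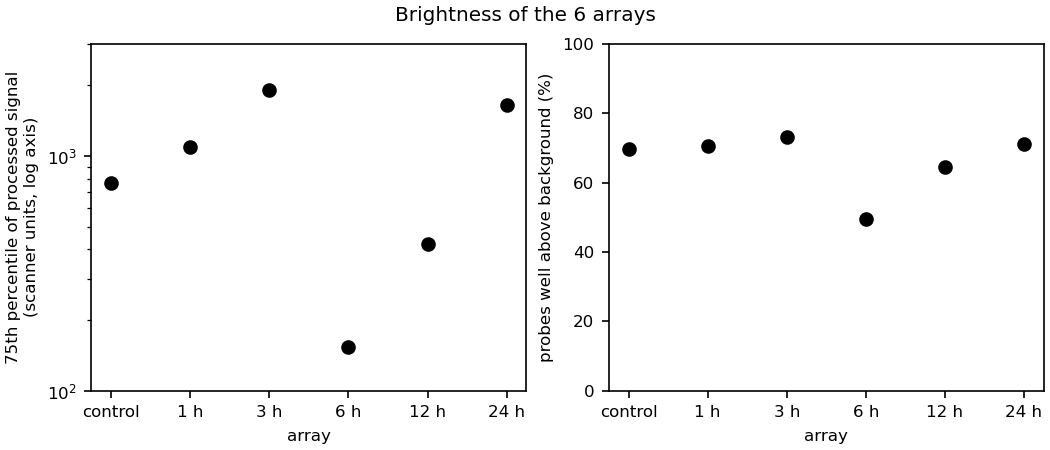
Brightness of the 6 arrays, 1 point per array. The left panel gives the 75th percentile of the processed signal on a log axis and the right panel the percentage of probes well above background; the 6 h array is lowest in both, at 153 units and 49.5%.

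Over the whole course, the cells' replication-dependent histone genes, which encode the histones made with newly replicated DNA, fell as a list, and genes of cholesterol synthesis and uptake rose as a list. Both calls were made at camera's preset correlation, and neither list passed with an estimated correlation. These histone RNAs lack a poly(A) tail. The median of 3 non-histone RNAs chosen as lacking one too lay -2.63 from matched lists at 12 h and -2.64 at 24 h. MALAT1 (-2.56 and -2.94) and RNU12 (-2.42 and -2.55) were low at these times. NEAT1, which also has a polyadenylated form, was at -0.16 and 0.56. Of 34 histone genes, 31 had a falling line, with a median fitted change from 0 to 24 h of -1.20. H1-4, a linker histone gene, was lower by -2.17 ± 0.77 at 6 h and by -2.72 ± 0.69 at 24 h, and H4C2, a core histone gene, by -3.01 at 24 h. The slope of 14 histone genes was below 0 at an adjusted p under 0.05 when adjusted over the list alone, and that of 0 when adjusted over all genes tested. By limma's camera the list had an adjusted p of 8.7e-18 at the preset correlation. The adjusted p = 0.0672 with an estimated correlation, 0.0285 for this list, at which no list passed. At the preset correlation the number of genes, not of arrays, sets the degrees of freedom. At that setting the call held without each array in turn, with a highest adjusted p of 2.32e-08 without the 24 h array. In 61 of 720 orders of the arrays some list of the 39 was as extreme among its own orders.

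Of 24 genes of cholesterol synthesis and uptake, 23 had a rising line, with a median fitted change of 1.06, uncorrected for the offset at 6 h and 12 h. Their measured median lay -0.003 from matched lists at 1 h, -0.06 at 3 h, 0.42 at 6 h, 0.35 at 12 h and 0.61 at 24 h. NSDHL, which removes methyl groups from sterol intermediates, was higher by 1.00 at 1 h, 1.61 at 3 h, 2.19 at 6 h, 2.39 at 12 h and 2.79 ± 0.69 at 24 h. MVD, an enzyme of the mevalonate pathway, was higher by 2.48 at 6 h and 2.30 at 24 h. One gene rose when adjusted over the list alone, and 0 did over all genes tested. The list's adjusted p was 5.98e-06, and adjusted p = 0.658 with an estimated correlation.

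**Figure D2:**
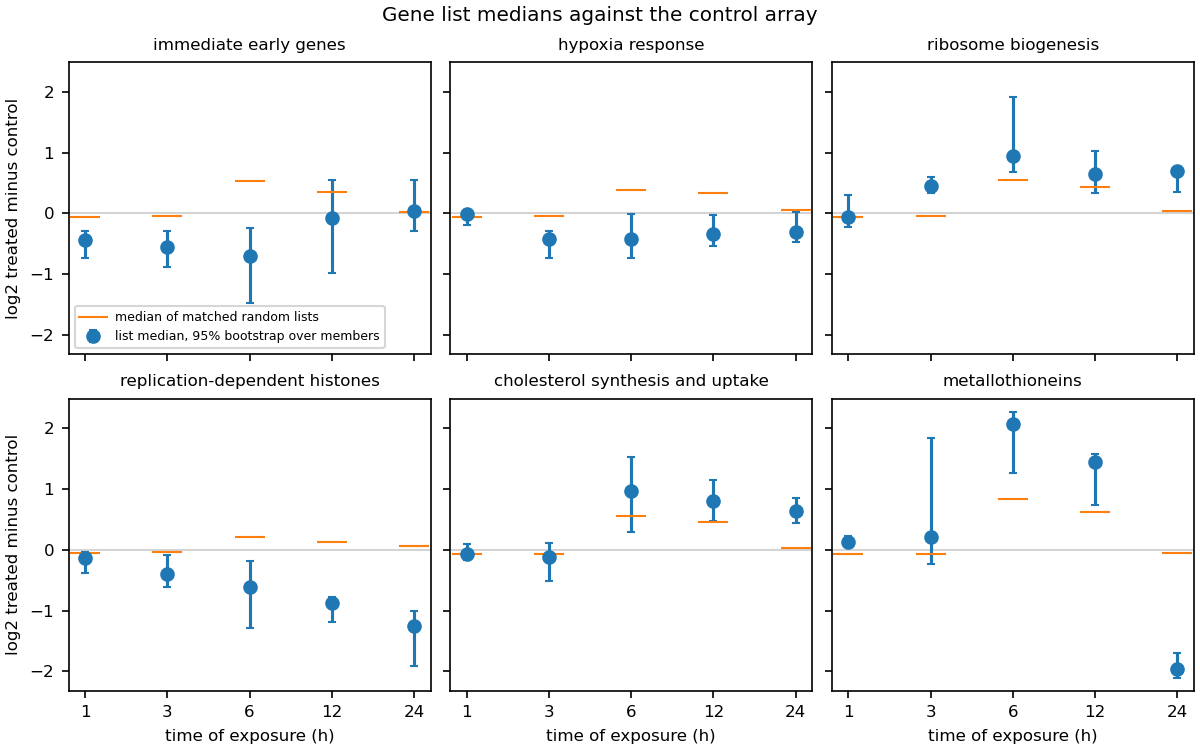
Median log2 difference from the control of 6 gene lists against hours of exposure. Points are list medians with 95% bootstrap intervals over members, and dashes are the medians of matched random lists; the histone median is -1.25 and the metallothionein median -1.96 at 24 h.

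Camera called 4 other lists at the preset correlation. Ribosome biogenesis genes rose as a list (adjusted p = 0.0365), with 21 of 24 lines rising. RRP12, a ribosome assembly factor, was higher by 1.37 at 3 h and 2.18 at 24 h, and NOP16, a nucleolar protein gene, by 2.56 at 6 h. Autophagy and lysosome genes rose as a list (adjusted p = 0.0365), with 21 of 23 lines rising. Their members included ATG12 at 1.71 at 12 h and CTSD at 1.38 at 24 h. WNT targets fell as a list (adjusted p = 0.0473), with 11 of 16 lines falling. ZNRF3, a ubiquitin ligase that acts on WNT receptors, was lower by -2.05 at 12 h, whereas its other probe was at -0.81. Markers of haematopoietic cells fell as a list (adjusted p = 0.0227), with 10 of 12 lines falling, among them CD79A at -1.36 and CD3E at -1.65 at 24 h. Only 7 of them were measured at 6 h. The cells were a hepatoma line, so this fall does not measure a share of blood cells. In these 4 lists 0 members rose or fell when adjusted over the list alone, except 1 WNT target that fell. Among lists not called, lines rose in 22 of 24 proteasome and 26 of 31 oxidative phosphorylation genes, and in 10 of 26 hypoxia genes. A count of rising lines, uncorrected for the offset at 6 h and 12 h, therefore does not set a called list apart. With an estimated correlation the adjusted p was 0.779 for ribosome biogenesis and 0.658 for the other 3 lists. Left-out arrays ended these calls. The adjusted p without the 24 h array was 0.23 for haematopoietic markers and 0.24 for autophagy, which had 0.0514 without the 3 h array. For ribosome biogenesis it was 0.195 without the control and 0.0556 without the 6 h array. For WNT targets it was 0.0593, 0.0583 and 0.122 without the 1 h, 3 h and 12 h arrays.

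No single gene passed the trend test. By limma 0 of 13619 genes had an adjusted p under 0.05, with 536 rising and 809 falling at an unadjusted p under 0.05. The smallest adjusted p was 0.243. The test of the linear and quadratic terms called 0 genes, with 790 at an unadjusted p under 0.05. The count of 1345 genes at an unadjusted p under 0.05 became 652 without the control, 723 without the 1 h array and 2827 without the 24 h array. Without the 6 h and 12 h arrays together, a choice made after seeing the data, 176 genes rose and 457 fell.

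The other 33 lists did not pass. Their adjusted p was 0.0871 for fatty acid and triglyceride synthesis, 0.0985 for the proteasome, 0.127 for the hypoxia response, 0.141 for AhR targets, 0.147 for PXR and CAR targets, 0.281 for heat shock proteins, and 0.273 for metallothioneins, gluconeogenesis, bile acid and FXR genes, glycolysis and DNA replication. It was 0.336 for oxidative phosphorylation and for fatty acid oxidation, 0.49 for epithelial and biliary markers, and 0.542 for p53 targets, AMPK subunits, NF-kappaB targets and NRF2 targets. It was 0.577 for TGF-beta targets, 0.579 for the circadian clock, 0.676 for mitosis, 0.679 for the acute phase, insulin signalling and iron handling, and 0.758 for the ATF4 response. It was 0.88 for endothelial markers, 0.931 for apoptosis regulators and hepatocyte secreted proteins, and 0.935 for the interferon response. It was 0.985 for endoplasmic reticulum chaperones, fibroblast and stellate cell markers, immediate early genes and cytosolic ribosomal proteins. Cytosolic ribosomal proteins had too few unsaturated members to be set against matched lists at any time. With quantile normalization metallothioneins (adjusted p = 0.012) and the hypoxia response (0.0303) fell as lists at the preset correlation, and both also did with normexp background (0.00105 and 0.00112). In the main values they had an adjusted p of 0.896 and 0.779 with an estimated correlation, and without the 24 h array metallothioneins rose (0.0201).

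Genes that the aryl hydrocarbon receptor (AhR) activates were among the most raised single genes. CYP1A1, a cytochrome P450 that oxidises polycyclic aromatic compounds, was higher by 0.44 ± 0.35 at 1 h, 2.76 ± 0.44 at 3 h, 3.53 ± 0.77 at 6 h, 3.89 ± 0.68 at 12 h and 3.16 ± 0.69 at 24 h. These last values are 6.77-fold at 3 h, 14.8-fold at 12 h and 8.93-fold at 24 h. AHRR, the repressor of the receptor, was higher by 1.42 at 3 h, 4.33 at 6 h, 3.53 at 12 h and 1.85 at 24 h. UGT1A6, a glucuronosyltransferase, was higher by 0.97 at 3 h and 1.71 at 24 h, and its other probe by 2.14 and 2.69. CYP1A2 lay within the error at each time (0.03 at 3 h and -0.57 at 24 h), and CYP1B1 was not well above background on the control array. Over the 12 AhR targets, 3 rose when adjusted over the list alone, while the list median was 0.12 above matched lists at 24 h and -0.75 from them at 6 h, where 4 of 10 measured members were at least 2-fold higher and 2 lower. The value at 6 h was below the range of matched lists, but in only 1 of 4 alternative settings (quantile or cyclic loess normalization, normexp background and the authors' deposited values). The median and the mean fitted change of the 12 targets were 0.79 and 1.07, whereas the measured median of 10 members at 24 h was 0.17. NQO1, a target of AhR and of NRF2, was at 0.46 at 3 h and -0.57 at 24 h, and HMOX1 at 0.43 and -0.35.

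**Figure D3:**
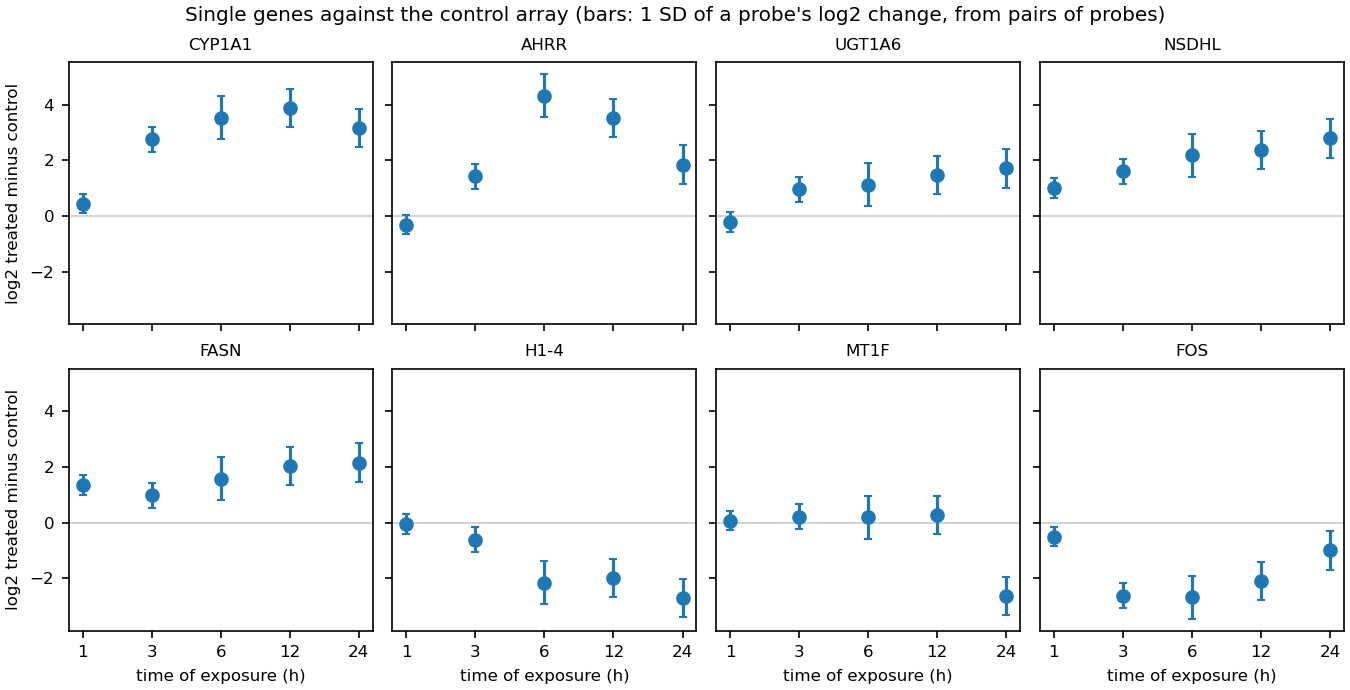
Log2 difference from the control of 8 genes against hours of exposure, 1 array per time. Bars are 1 SD of a single probe's difference, from pairs of probes; CYP1A1 lies at 2.76 or above from 3 h on, and MT1F lies near 0 until 12 h and at -2.65 at 24 h.

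At 1 h few genes differed, and the median of immediate early genes, which encode short-lived regulators induced by growth and stress signals, was below the range of matched lists. Of 13132 measured genes, 295 were at least 2-fold higher and 87 lower, and with normexp background 111 and 37. The median of 23 immediate early genes was -0.44, below all 10000 matched lists, with 3 at least 2-fold lower. DUSP1, a phosphatase of MAP kinases, was at -1.20. The ATF4 and amino acid response list lay 0.22 below matched lists, outside their range in 2 of the 4 alternative settings, and DDIT4, an inhibitor of the kinase complex mTORC1, was at -1.45. Among genes at least 1.5-fold apart in the same direction at a neighbouring time, a condition also used at the later times, the most raised were C2orf68 (2.56), GH2 (2.53), ETNK2 (2.46), UCP3 (2.07), ADAMTS7 (1.92) and MIR4453HG (1.88), but the other probes of GH2, UCP3 and ADAMTS7 were at -0.19, -0.59 and -0.48. HSD17B6 (-2.73), CDCP2 (-2.58), CAPN13 (-2.52), STAT5A (-2.23), ANKLE1 (-1.89) and ODF4 (-1.85) were most lowered, and the other probe of STAT5A was at 0.02. The other 36 measured lists lay within the range of matched lists.

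At 3 h the medians of the immediate early, hypoxia and ATF4 lists were below the range of matched lists, and those of ribosome biogenesis, the proteasome, NRF2 targets and oxidative phosphorylation were above it. Of 13050 measured genes, 423 were at least 2-fold higher and 386 lower, and with normexp background 166 and 350. Immediate early genes had a median of -0.56, with 6 of 23 at least 2-fold lower and FOS, a subunit of the transcription factor AP-1, at -2.62. The hypoxia list had a median of -0.43, with ANKRD37 at -2.47 and DDIT4 at -2.15. The ATF4 list had a median of -0.49, with MTHFD2, a mitochondrial folate enzyme, at -1.09. Ribosome biogenesis had a median of 0.45, above all matched lists, the NRF2 list of 0.34, the proteasome of 0.22 and oxidative phosphorylation of 0.16. Members at least 2-fold higher were 4 of 20 for ribosome biogenesis, 1 of 15 for NRF2, 1 of 21 for the proteasome and 0 of 25 for oxidative phosphorylation, and the 95% bootstrap intervals of the NRF2 and oxidative phosphorylation medians spanned 0. Histones (-0.39), mitosis (-0.26), gluconeogenesis (-0.39), PXR and CAR targets (-0.45) and epithelial markers (-0.47) were also below the range, and iron handling (0.27) above it. The bootstrap intervals of gluconeogenesis, PXR and CAR targets and iron handling also spanned 0. In the 4 alternative settings mitosis was outside the range in 2 and iron handling in 0. PCK1, the first committed enzyme of gluconeogenesis, was at -2.07, while its other probe was at 0.31. Besides CYP1A1, the most raised genes under this condition were WDR46 (2.66), MED18 (2.59), ETNK2 (2.47), MAB21L2 (2.44) and S100A5 (2.40). The most lowered were FUT1 (-3.80), PIM1 (-3.02), CCNG2 (-3.00), DEPP1 (-2.90), STAT5A (-2.89) and YPEL2 (-2.64). PIM1 encodes a short-lived kinase. The other probes of CCNG2, DEPP1 and YPEL2 were at -1.23, -2.00 and -3.20, and that of STAT5A at 0.11.

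The 6 h and 12 h arrays were the dimmest. At 6 h, of 10639 measured genes, 2438 were at least 2-fold higher and 1069 lower, and at 12 h, of 12544, 1642 and 978. Quantile normalization gave 1553 higher at 6 h and 1057 at 12 h. Metallothionein genes, which encode small metal-binding proteins, lay 1.23 above matched lists at 6 h and 0.82 above them at 12 h, and 0.63 and 0.44 above them with quantile normalization. The list of 12 also holds SLC30A1, a zinc transporter gene. Of the 11 metallothionein genes, the 4 saturated on no array had a median 0.137 above matched lists at 6 h and 0.052 above them at 12 h. MT1M was at 1.76 and 1.19, and MT1F at 0.18 and 0.28. Cholesterol genes lay 0.42 and 0.35 above matched lists and the proteasome 0.47 and 0.30 above them. Below them lay immediate early genes (by -1.24 and -0.43), the hypoxia response (-0.81 and -0.68), histones (-0.82 and -1.01), WNT targets (-0.61 and -1.28), gluconeogenesis (-0.71 and -0.55), fatty acid oxidation (-0.60 and -0.44) and epithelial and biliary markers (-1.17 and -0.89). At 6 h, 5 of 13 measured WNT targets were at least 2-fold higher and 5 lower. Of 6 epithelial and biliary markers measured at 6 h, 2 were at least 2-fold higher and 1 lower. The ATF4 list (-1.16) and mitosis (-0.44) were below the range at 6 h, and p53 targets (-0.40) and the circadian clock (-0.43) at 12 h. Of these lists, cholesterol genes at 6 h were outside the range in 3 of the 4 alternative settings, and the proteasome, WNT targets and fatty acid oxidation at 6 h in 2. Fatty acid oxidation, epithelial and biliary markers and the circadian clock at 12 h were outside it in 1, and the proteasome and p53 targets at 12 h in 0. MYC, a growth-promoting transcription factor, was at -2.88 at 6 h by its brightest probe and at 0.16 by another.

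Under the same condition, single genes at 6 h included MYOF (5.19), TMEFF2 (4.64), MAGEC1 (4.62), PAGE4 (4.15) and MTCP1 (3.89) among the most raised besides AHRR. PDIA4, a protein disulfide isomerase of the endoplasmic reticulum, was lowest at -5.05 ± 0.77, followed by SOX9 (-4.04), TSPAN14 (-4.03), BTG1 (-3.82), PIM1 (-3.75) and MACF1 (-3.74). Other probes of MACF1 lay between 0.24 and 0.26. At 12 h RGS5 (4.29), MAB21L2 (4.21), MYCNOS (3.39) and ADRB3 (3.23) were most raised besides CYP1A1 and AHRR. PDIA4 (-4.54), NFKBIZ (-4.12), POGZ (-4.06), TSPAN14 (-4.03), KDM3B (-3.60) and IL1RN (-3.57) were most lowered, with another probe of POGZ at -2.53 and of IL1RN at 1.17. Other probes of TSPAN14 lay between -0.23 and 0.71 at 12 h.

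At 24 h the medians of metallothioneins and histones were furthest below matched lists, and those of ribosome biogenesis and cholesterol genes furthest above them. Of 13046 measured genes, 950 were at least 2-fold higher and 1209 lower, and with quantile normalization 1122 and 1036. The metallothionein list had a median of -1.96, with 9 of 11 measured members at least 2-fold lower, among them MT1F at -2.65 and MT1M at -2.58. The 1 member at least 2-fold higher was SLC30A1, at 1.02. Histones had a median of -1.25, with 22 of 33 at least 2-fold lower. DNA replication genes had a median of -0.40, and RRM2, a subunit of ribonucleotide reductase, was at -2.00. PXR and CAR targets had a median of -0.99 (95% bootstrap interval -1.92 to 0.14), with 6 of 12 members at least 2-fold lower and 1 higher. GSTA1, a glutathione transferase, was at -3.12, and ABCB1, a drug efflux pump, at 2.39. The hypoxia response (-0.31), gluconeogenesis (-0.50) and haematopoietic markers (-0.55) were also below the range, in 3, 2 and 0 of the 4 alternative settings. The bootstrap intervals of the hypoxia response and of gluconeogenesis spanned 0.

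Above the range at 24 h were ribosome biogenesis (0.69), cholesterol genes (0.64), AMPK subunits and partners (0.55), autophagy and lysosome (0.45), fatty acid and triglyceride synthesis (0.39, with 7 of 19 members at least 2-fold higher) and the proteasome (0.30). The bootstrap intervals of AMPK, of fatty acid and triglyceride synthesis and of the proteasome spanned 0. AMPK and autophagy were outside the range in 3 of the 4 alternative settings. FASN, the fatty acid synthase, was at 2.16 ± 0.69, SCD, the stearoyl-CoA desaturase, at 2.57 with other probes between 0.70 and 0.86, and ACACA at 1.49. PRKAA1, a catalytic subunit of the kinase AMPK, was at 0.66, within the error, and PRKAA2 at -0.49. Among genes also at least 1.5-fold apart in the same direction at 12 h, the most raised were WDR46 (3.41), CYP1A1, NSDHL, TPRG1L (2.61), SEC24C (5.64-fold) and ZSCAN21 (2.46). The most lowered were RNF182 (-4.14), H4C4 (-3.93), H2BC5 (-3.77), POGZ (-3.72), PDIA4 (-3.62) and ZNF71 (-3.52), and the other probe of H2BC5 was at -0.99.

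Several abundant liver transcripts could not be followed. The brightest probes of ALB, GDF15, FTL, APOA2 and RPLP2 were saturated on the control array or a treated one at each time. For 13 lists the median stayed within the range of matched lists at each time at which enough members were measured. These were endoplasmic reticulum chaperones, heat shock proteins, glycolysis, insulin signalling, bile acid and FXR genes, hepatocyte secreted proteins, the acute phase, NF-kappaB targets, the interferon response, TGF-beta targets, apoptosis regulators, and markers of fibroblasts and of endothelial cells.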

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

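The tests of array brightness, S phase and array order for histones, of each explanation for metallothioneins, of probe agreement and of the 5' signal against the other treated arrays were chosen after the result, or values close to it, had been seen. After their values were first seen, the verdict on SLC30A1 was corrected to its stated bounds, a minimum number of members was dropped from the poly(A) test, the bound for S phase was loosened, the order test was widened from histones to all 39 lists, and the tests of saturation and of the 5' signal were each split into parts.

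Metallothionein genes moved in opposite directions at different times, which drew attention to them: their median lay 1.23 above matched lists at 6 h, 0.82 above at 12 h and -1.90 from them at 24 h. Each time has 1 array and the difference was not tested. For the lower values at 24 h, saturation and brightness are argued against by the 4 members saturated on no array, with a median of -2.26. For the higher values they stay open: the median of these 4 was 0.137 above matched lists at 6 h and 0.052 above them at 12 h, and 2 of the 4 lay above them by more than the error at 6 h and 0 at 12 h. Near-identical paralogs may share probe signal. SLC30A1, a single-copy gene of the same metal-responsive regulator and itself on the list, was at 1.02 at 24 h. This is opposite to the metallothioneins and decides nothing about shared signal. MT1F was at 0.18 at 6 h, unlike most other metallothionein genes, so its signal was not wholly shared there. At 24 h it was at -2.65, low like the other metallothionein genes. MT3 was at -0.72 at 6 h and -0.98 at 24 h. Probe sequences were not compared, so shared signal at 24 h stays open. Time in culture, with no matched control, and a response of the cells stay open.

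The fall of replication-dependent histones may be technical. Array brightness is argued against, since histones lay below matched lists by -0.82 on the dimmest array and by -1.31 on the bright 24 h array. Lower capture of RNA without a poly(A) tail remains a candidate explanation. The 3 non-histone RNAs chosen as lacking one had a median of -2.64 from matched lists at 24 h, with MALAT1 at -2.94 and RNU12 at -2.55. NEAT1, which also has a polyadenylated form, was at 0.56. Polyadenylated replication-independent histone genes lay -0.38, -0.26 and -0.18 from matched lists at 6, 12 and 24 h, within their range. Fewer cells in S phase stay open. DNA replication genes lay 0.10, 0.01, 0.0119 and -0.44 from matched lists at 3, 6, 12 and 24 h. Histones lay -0.36, -0.82, -1.01 and -1.31 from them, so only the 24 h values go together. Chance order of the arrays is not excluded: 2 of the 720 orders gave histones as large a slope, with a real sum of 4.61 and a highest other of 4.62, and in 61 orders some list of the 39 was as extreme.

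The 6 h and 12 h arrays stood apart from the others on the first principal component, which held 59.6% of the variance over 19016 probes. Loss of signal from the 5' part of transcripts is argued against as the difference from the control. The median change of the 3' probe minus the 5' probe was 0.007 at 6 h and 0.048 at 12 h, and -0.13 and -0.03 after quantile normalization, under the bound of 0.1. As the difference from the other treated arrays it stays open. At 1, 3 and 24 h the median was -0.19, -0.26 and -0.28, and the smaller of the 6 h and 12 h values lay above the largest of these by 0.201, or by 0.0625 after quantile normalization. Lower brightness could not be settled, because in bright probes the SD of the change at 6 h and 12 h was 1.05 times that at 24 h (95% bootstrap interval 1.01 to 1.08), between the bounds set for either answer. A transient response of the cells could not be settled either, since the mean correlation between probes of a gene at 6 h and 12 h was higher than at 24 h by 0.0653 (0.0275 to 0.107). After quantile normalization this correlation was 0.465 at 1 h, 0.423 at 3 h, 0.417 at 6 h, 0.394 at 12 h and 0.340 at 24 h. At 6 h and 12 h it was thus below that at 1 h and 3 h. Control spots were dim as well, with a bright-corner signal of 1790 at 6 h and 3370 at 12 h against 10275 on the control array. The dimness therefore did not come from the cells' RNA alone. Brightness, slide and time cannot be told apart for the changes in expression, because each time has 1 array and no slide is named.

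Chance order is not excluded for the count of genes with a trend: 27 of 100 orders of the arrays gave at least the real 1345 genes at an unadjusted p under 0.05, and the highest other order gave 4799. Why that order gave more genes was not tested. Probes with no gene symbol entered no comparison of genes or lists, but were among the probes of the principal component and of the brightness test. They were at least 8-fold above the control, with a neighbouring time also higher, in 34 cases at 6 h and 23 at 12 h.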

How the results depend on the processing

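Cyclic loess normalization, the settings for saturated genes and leaving out the 6 h and 12 h arrays were chosen after seeing the data; the cause of each shift below was not tested unless stated. The trend test called 0 genes in each alternative fixed beforehand and without each array in turn (0 to 0), as did the smooth test in those in which it was run, and the trend test called 633 without the 6 h and 12 h arrays. Camera called 6 lists, 4 to 9 without single arrays, 10 with normexp, 11 without the 6 h and 12 h arrays and 0 with an estimated correlation. With normexp the call was lost for haematopoietic markers, ribosome biogenesis and autophagy, and with quantile or cyclic loess normalization for autophagy and WNT targets. Falls were gained for metallothioneins (0.012) and hypoxia (0.0303) with quantile normalization, for hypoxia (0.0438) and glycolysis (0.0458) with cyclic loess, and for metallothioneins (0.00105), hypoxia (0.00112), glycolysis and DNA replication (0.0148), hepatocyte secreted proteins (0.033) and mitosis (0.0346) with normexp. Without the 6 h and 12 h arrays the call was lost for WNT targets (0.113) and ribosome biogenesis (0.0763). There rises were gained for AhR targets and fatty acid and triglyceride synthesis (0.0455), and falls for PXR and CAR targets (0.0311), DNA replication (0.0264), hepatocyte secreted proteins (0.022) and metallothioneins (9.68e-08). The trend of cytosolic ribosomal proteins turned downward with normexp (adjusted p, signed by direction, -0.033) and without the 6 h and 12 h arrays (-1.13e-07), and that of metallothioneins ranged from -0.255 to 0.0201 without single arrays, turning upward without the 24 h array. Too few cytosolic ribosomal protein genes were free of saturation for that list to be tested without saturated genes. Its trend values may therefore show the scaling of saturated probes, not the RNA. Genes at least 2-fold higher numbered 1553 at 6 h and 1057 at 12 h with quantile normalization, and 1072 at 12 h with cyclic loess. With normexp they numbered 111, 166, 2471 and 553 at 1, 3, 12 and 24 h, and those lower 37, 1776 and 564 at 1, 6 and 12 h. Without the background filter, higher and lower genes numbered 582 and 436 at 1 h, 1035 and 692 at 3 h and 6111 and 1787 at 6 h, with 2493 higher at 12 h, where more genes were counted. At 1.5-fold they numbered 1049 and 876, 1419 and 1456, 4155 and 1889, 3922 and 1999, and 2500 and 2540 at the 5 times, a wider threshold by construction. With saturated genes kept, 584 were lower at 3 h. The share of higher among changed genes was 69.5% at 6 h and 62.7% at 12 h, and became 55.7% and 48.8% with quantile normalization, 57.3% and 49.0% with cyclic loess and 55.5% and 81.4% with normexp, which also moved it from 52.3% to 32.2% at 3 h, where cyclic loess gave 42.8%. At 24 h it was 44.0%, and 52.0% with quantile normalization. With the authors' deposited values 5 lists, against 2, lay outside the range of matched lists at 1 h. Single genes that changed sign with normexp at 6 h included CPT2 (0.31), SLC2A1 (-0.25), PIK3CA (0.62), STAT3 (0.46), CRY1 (0.15) and KRT19 (-0.44), and SLC2A2 (0.18) at 12 h. With the mean of a gene's probes they were MT1E (-0.53) and MYC (0.35) at 12 h and SOCS3 at 3 h (-0.68) and 6 h (-0.67). The slide as a block was not run, since the files name no slide. Positions repeat, so the arrays came from at least 2 slides. The control and 6 h arrays share a position, as do the 1 h and 24 h arrays, so neither pair shared a slide. The 6 h comparison is therefore between slides, and slide and time of exposure may be confounded at other times too. No paired analysis was possible because each group holds 1 array. The dim 6 h array limits low genes most: 2787 genes were above background on the control array alone.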

Other observations

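The list of short-lived transcripts was drawn up after the fall of immediate early genes had been seen, but before its own values were.

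A hypothesis is that short-lived transcripts were lower in general at the early times, as a reduced rate of transcription could produce. It was tested on 37 short-lived regulatory transcripts outside the immediate early, ATF4 and hypoxia lists. Their median was -0.27 at 3 h, at percentile 0.35 of matched lists, with 9 of 34 measured members at least 2-fold lower. It lay -0.33 from matched lists at 1 h, -1.05 at 6 h, -0.45 at 12 h and -0.13 at 24 h, where its percentile was 15.2. With the 35 genes on none of the 39 lists the percentile at 3 h was 0.81. The test is consistent with the hypothesis, but the genes were chosen by hand, transcription was not measured, and all times share 1 control array, so a control high in these transcripts could give the same values.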
